A study of Mus musculus with 110 samples.

How the data were processed

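The 110 mouse samples were 75 RNA-seq libraries and 35 ChIP-seq samples, of which 12 were inputs without a peak list used here. Per the labels' protocols, naive CD4+ T cells were sorted from 6- to 8-week-old mice and activated on plate-bound anti-CD3 and anti-CD28, and libraries were sequenced as single reads of 50 cycles. For Toxoplasma, per the same protocols, about equal numbers of WT (CD45.1) and Tbx21-/- (CD45.2) naive cells were given to hosts lacking Rag2.

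The RNA values were TPM, which the authors made with kallisto 0.42.4 after base calling with CASAVA 1.8.2, per the submitters' processing notes. Each peak carried the MACS 1.4.3 score that the authors deposited after alignment with Bowtie 1.1.2, per the same notes. Those notes also name STAR 2.4.2a and bedtools 2.15 and 2.24, and the builds mm10 and GRCm38. Scores served only to filter peaks within a list. TPM keeps no read number, so the depth per library is unknown and no interval for counting error was given for RNA. A gene listed at 0 may have been below detection.

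What follows was computed here. The TPM table had 31990 entries, of which 92 were spike-in transcripts (highest summed value 0.01 TPM, above 0 in 1 library) and were left out. A further 193 repeated a gene symbol and were summed, leaving 31705 genes. Values were taken as log2(TPM + 1). This shrinks differences of genes near 1 TPM. Genes with a mean of at least 1 TPM in at least 1 group of a fit were tested with limma 3.58.1 in R 4.3.3 (trend = TRUE), in 4 fits: 72 h (29 libraries, 20 residual degrees of freedom, 13277 genes), 6 and 24 h with naive cells (26 libraries, 14, 13310 genes), Toxoplasma (8 libraries, 4, 13269 genes) and LCMV (12 libraries, 8, 13252 genes). Each fit held 1 coefficient per group, and the 30 comparisons were contrasts of these, 4 of them interactions. For Tbx21-/- cells with IFN-γ at 72 h, the library with IFN-γ alone and the 2 Iso libraries were averaged as 3 libraries of 1 group, while for the antibody doses Iso kept its own coefficient (19 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Means and SD are of TPM over the libraries of a group, and log2 differences come from the fit.

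Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Members past the threshold are counted over all genes and, again, adjusted over the list alone. The 24 lists fixed before the data were examined were type I interferon-stimulated genes, IFN-γ, class II and GTPase genes, type I interferon ligands, interferon receptors with JAK-STAT and IRF factors, nucleic acid sensors, Th1, Th2, Th17, follicular helper, regulatory, cytotoxic, naive and resting, activation, co-inhibitory and cell cycle genes, immediate early and heat shock genes, genes of sex, and markers of B cells, CD8 T cells, macrophages, dendritic cells, NK cells, granulocytes and erythroid cells. They came from general knowledge, not a database. Lists may share genes: 9 of 10 dendritic markers are in no other fixed list. Another 2 lists held genes induced in WT cells by IFN-β (289 genes) or IFN-γ (81 genes) at 24 h with a log2 change of at least 1. Of the former, 76 are also type I list members and 72 are shared with the latter. Genes of sex, 1 of which passed the filter at 72 h, were read as levels only.

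Genes named in the report followed a rule set before the data were examined: Tbx21, Ifng, Irf7, Irf9, Irf1, Stat1, Stat2 and Ifnb1 always; the 10 largest rises and 10 largest falls past the threshold, with a mean of at least 5 TPM and no overlap between libraries of the groups; and up to 4 members of each list with the smallest p. Those printed were picked for space, after their values were seen.

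Peak lists were compared with bedtools 2.31.1, an overlap being at least 1 bp, with 95% Wilson intervals that cover counting error only. A gene counted as near a peak when the peak midpoint lay within 20 kb of either end of its span, because the gene table gave no strand; the planned distance was to the start site. Positions were found for 12526 of 13277 genes (94.3%), 571 through an older symbol. Nearness to lists (437 pairs) and to changed genes (138 pairs) was tested with Fisher's exact test in SciPy 1.17.1 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) and adjusted over the pairs. Figures used matplotlib 3.10.9.

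Alternatives fixed before the data were examined were a pseudocount of 0.25, no filter, quantile normalization, a fit to only the libraries of the compared groups, leaving out each library in turn, the library series as a covariate, the IFN-γ library or the Iso libraries alone, an estimated correlation for lists, peaks at or above the median score, overlap of at least 0.5 of the shorter peak, and gene distances of 5 and 100 kb. Added after results were seen were fits within the shared series, without the 2 lowest-numbered libraries, with 2 of the 4 neutral libraries at 6 h, with the macrophage marker mean as a covariate, and with sets of consecutive library numbers as blocks (Toxoplasma, anti-IFNAR, and WT cells at 6 and 24 h). Where a left-out library left a group with 1 library, that library was assumed to vary like the other groups of the fit. A result past the threshold in neither setting was counted as unchanged, and a count as moved when it differed by over 1.5 times. Libraries were also reassigned to groups in all or up to 100 other ways.

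The method was tested on simulated data with 200 altered genes in the same layout. For Tbx21-/- against WT with IFN-γ at 72 h it recovered 55.2, 95.5 and 98.5% of genes altered by a log2 of 0.5, 1 and 2, with 8 false calls among 174. For Toxoplasma PEC recovery was 34.3, 80.6 and 93.9% (3 false among 142), for LCMV Armstrong 49.3, 82.1 and 98.5% (6 among 159), for anti-IFNAR dose 10 it was 35.8, 89.6 and 98.5% (9 among 158), and for IFN-β at 24 h 26.9, 89.6 and 97.0% (11 among 153). Of 672 list tests, 315 passed with the preset correlation.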

Results

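The series measured RNA and chromatin binding in CD4+ T cells of C57BL/6 mice that were wild type (WT) or lacked Tbx21, the gene for the transcription factor T-bet. T-bet directs CD4+ T cells to the T helper 1 (Th1) fate. The series title asks how T-bet limits the type I interferon programme in Th1 cells. RNA-seq covered 75 libraries in 30 groups, and ChIP-seq 35 samples. Naive CD4+ T cells were activated for 6, 24 or 72 h without added interferon (neutral), with IFN-γ (100 ng/mL) or with IFN-β (5000 U/mL). At 72 h the groups held 4 WT neutral, 3 WT IFN-γ, 5 WT IFN-β, 4 Tbx21-/- neutral and 4 Tbx21-/- IFN-β libraries. A further 9 Tbx21-/- libraries were treated with IFN-γ for 72 h: 1 with IFN-γ alone, 2 in an arm titled Iso, and 2 at each of the doses 0.1, 1 and 10 of an antibody against the type I interferon receptor (anti-IFNAR), whose unit the labels did not give. At 6 and 24 h each group held 2 libraries, except 4 for WT neutral at 6 h, without a Tbx21-/- neutral group. Naive cells gave 2 libraries per genotype. For Toxoplasma gondii (strain ME49), WT and Tbx21-/- cells were transferred together into mice lacking Rag2. Spleen and a site labelled PEC each gave 2 libraries per genotype. For lymphocytic choriomeningitis virus (LCMV), strains Armstrong and clone 13 gave 3 libraries per genotype each, titled Tmem. Other RNA titles read CD4, so the cells may differ in kind.

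TPM scales transcripts to a fixed sum. Each library held 11115 to 12829 genes at 1 TPM or more and 3.7 to 9.0% mitochondrial TPM. No library duplicated another, and 62 of the 75 libraries lay closest to a library of their own group. No label says whether libraries of a group came from separate mice or cultures. P-values thus measure only the spread between these libraries, which may be technical. Library numbers in the titles fell into 4 series at 72 h. Only 1 of them, here called the shared series, held both genotypes (4 WT and 5 Tbx21-/- libraries). Of the others, 1 held 6 and 1 held 2 WT libraries, and the last held 12 Tbx21-/- libraries. Genotype differences at 72 h are also given within the shared series and with the series as a covariate.

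Tbx21 (ENSMUSG00000001444, GRCm38 chromosome 11, 97098007 to 97115331) was lower in Tbx21-/- libraries wherever WT cells expressed it. At 72 h it measured 27.9 ± 4.25 TPM (SD, n = 4) in WT and 5.48 ± 1.28 (n = 4) in Tbx21-/- neutral cultures. With IFN-β it was 29.0 ± 4.81 (n = 5) against 5.10 ± 0.150 (n = 4). With IFN-γ it was 28.3 ± 1.27 (n = 3) against 12.2 ± 0.551 (n = 3), the smallest of these gaps. At 6 h WT cells rose from 0.295 ± 0.180 TPM in neutral culture (n = 4) to 31.1 ± 0.877 with IFN-γ and 15.6 ± 1.75 with IFN-β, against 5.69 ± 0.474 and 2.15 ± 0.240 in Tbx21-/- cells (n = 2 each). At 24 h the corresponding WT levels were 0.34 ± 0.184, 38.7 ± 3.11 and 11.4 ± 3.97, against 4.55 ± 0.191 and 1.92 ± 0.460 (n = 2 each). Naive cells barely expressed the gene in either genotype (0.33 ± 0.382 in WT and 0.985 ± 0.644 in Tbx21-/-, adjusted p = 0.431), so it could not check those labels. In Toxoplasma infection it was 104 ± 2.52 against 6.21 ± 1.45 in the spleen and 83.9 ± 13.2 against 4.78 ± 0.608 in PEC (n = 2 each). In LCMV infection it was 31.0 ± 2.16 against 3.29 ± 0.680 with Armstrong and 40.4 ± 9.89 against 4.38 ± 0.830 with clone 13 (n = 3 each). TPM sums all transcripts of the gene, so transcripts that keep part of it still count in Tbx21-/- cells.

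**Figure D1:**
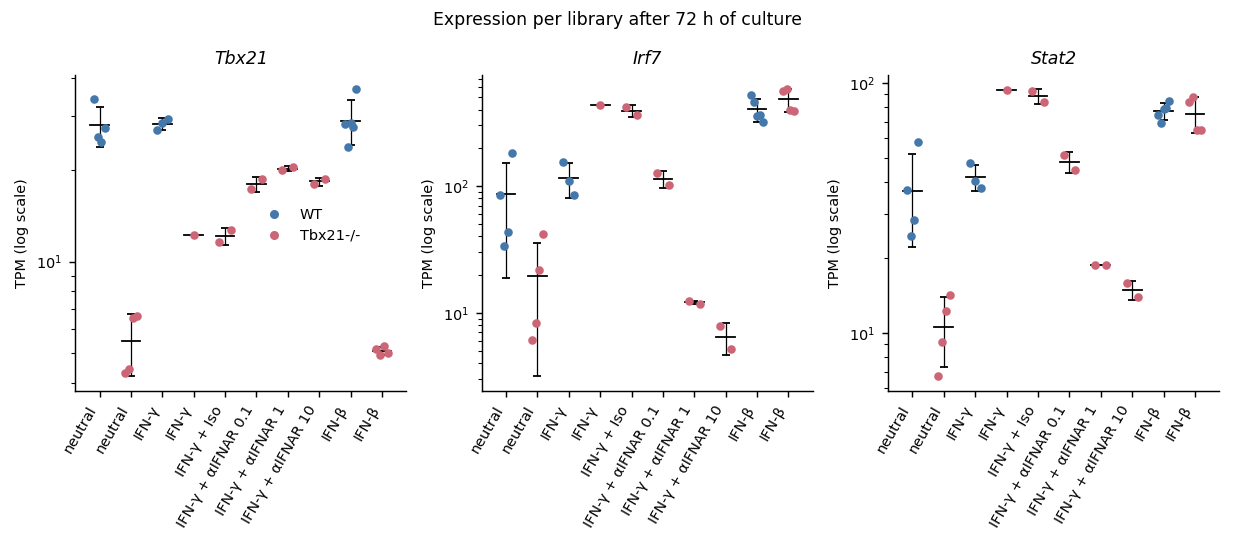
TPM of Tbx21, Irf7 and Stat2 in each 72 h library on a log axis, by group. Black lines are means, bars SD, blue points WT and red Tbx21-/-. Tbx21 is lower in Tbx21-/- groups, while Irf7 and Stat2 are low in Tbx21-/- neutral cultures, high with either interferon and low again at anti-IFNAR doses 1 and 10.

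In WT cells, IFN-γ raised some Th1 and cytotoxic genes at 72 h. Ly6c2, a surface marker of effector cells, rose from 10.2 ± 5.47 TPM (n = 4) to 76.1 ± 37.9 (n = 3; log2 2.81 ± 0.39 SE, adjusted p = 0.000183). Nkg7, a cytotoxic granule gene, rose from 46.5 ± 10.59 to 139 ± 20.0 TPM (log2 1.58, adjusted p = 0.00334), and Klrk1, which encodes the receptor NKG2D, by a log2 change of 2.01 (adjusted p = 0.000101). Ifng itself rose from 2.39 ± 1.00 to 14.5 ± 10.9 TPM (log2 1.84, adjusted p = 0.0129). Haao (log2 1.77) and Ctsw (1.47) also rose, whereas Akr1c18 (-1.97), Nrp1 (-1.38), Ccr4 (-1.35), a Th2 chemokine receptor, and the GTPase Gbp2 (-0.89, adjusted p = 0.0311) fell. Interferon regulators did not pass: Stat1 measured 397 ± 48.4 TPM against 416 ± 51.5 in neutral culture (adjusted p = 0.718), Irf1 156 ± 23.9 against 187 ± 24.0 (0.534), Irf7 116 ± 35.9 against 85.7 ± 67.1 (0.379), Irf9 43.5 ± 5.95 against 36.1 ± 4.19 (0.197) and Stat2 42.0 ± 5.07 against 37.0 ± 15.0 (0.502). Of 29 Th1 genes measured, 10 rose and 0 fell (13 and 1 adjusted over the list alone, below: list-wise), and of 15 cytotoxic genes 6 rose and 0 fell (7 and 0 list-wise). The set test camera gave adjusted p = 8.62e-07 and 0.000144 for these lists, and 0.0319 for each with an estimated correlation between genes (below: when estimated). Of 77 type I interferon-stimulated genes 2 rose (1 list-wise), with a median log2 change of 0.16; camera gave adjusted p = 0.0101, and 0.991 when estimated. Cell cycle genes tended down, 9 of 40 falling (15 lower and 1 higher list-wise, camera adjusted p = 1.52e-05, and 0.358 when estimated). In all, 686 of 13277 genes were higher and 629 lower. That total of 1315 came to 149 with only the libraries of these groups, to 19 within the shared series, to 3377 with the series as a covariate and to 669 without WT IFN-γ replicate 1. That series holds 1 library of each group, too few to judge these calls; there the Ifng difference was -0.40 and Ly6c2, Haao, Nkg7, Ctsw, Akr1c18, Nrp1 and Gbp2 did not pass. With only the compared libraries the calls of Ifng, Klrk1, Ctsw, Nrp1 and Ccr4 were lost.

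IFN-β produced a broad interferon response in WT cells at 72 h. Of the 77 type I interferon-stimulated genes, 76 rose and 0 fell, the same list-wise, with a median log2 change of 1.63 (camera adjusted p = 9.59e-55, and 0.0355 when estimated). Plac8 rose from 2.89 ± 2.00 TPM (n = 4) to 460 ± 112 (n = 5; log2 7.02 ± 0.28 SE, adjusted p = 3.71e-14). The chemokine gene Cxcl10 rose by 4.50, Ly6c2 by 4.47, the RNA sensor gene Oas1a by 4.11, Ifit3 by 3.89 and the antiviral gene Rsad2 by 3.73. Irf7, the master regulator of type I interferon genes, rose from 85.7 ± 67.1 to 403 ± 83.3 TPM (log2 2.51, adjusted p = 0.000104), Stat2 from 37.0 ± 15.0 to 77.0 ± 5.83 (1.11), Stat1 from 416 ± 51.5 to 540 ± 34.04 (0.38, adjusted p = 0.00137) and Ifng from 2.39 ± 1.00 to 18.8 ± 7.03 (2.52). Nucleic acid sensors rose with them, 11 of 16 passing and 0 falling (12 and 0 list-wise, camera adjusted p = 1.08e-07, and 0.0212 when estimated). Of 29 Th1 genes 14 rose and 5 fell (17 and 6 list-wise, camera adjusted p = 0.000303, and 0.0907 when estimated). Immediate early and heat shock genes, a list of handling effects (below: heat shock genes), had 9 of 15 higher (11 list-wise, camera adjusted p = 3.09e-05, and 0.0907 when estimated). Largest falls were in Aldoc, a glycolytic enzyme (61.1 ± 12.8 to 6.19 ± 4.32 TPM, log2 -3.27), the oxygen sensor Egln3 (-2.56) and the glucose transporter Slc2a3 (-2.55). Altogether 1897 genes were higher and 1471 lower, a total of 3368 that was 385 within the shared series. Against IFN-γ, IFN-β gave higher values for 72 of the 77 type I genes (74 list-wise; median log2 1.44, camera adjusted p = 1.62e-31, and 0.238 when estimated). Heat shock genes had 8 of 15 higher (9 list-wise, camera adjusted p = 0.00796, and 0.543 when estimated). Plac8 (460 ± 112 against 5.83 ± 2.92 TPM, log2 6.12), Cxcl10 (4.71) and Ifit3 (4.10) led, and Irf7 (1.81), Stat2 (0.86), Irf9 (0.49) and Stat1 (0.45) were higher too. Aldoc (-4.11), Selenbp1 (-3.85) and Slc2a3 (-3.65) were lower with IFN-β. That comparison called 2685 genes higher and 2173 lower, a total of 4858 that was 1830 within the series.

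Loss of T-bet in neutral culture lowered interferon-stimulated genes of both kinds at 72 h. Stat1 fell from 416 ± 51.5 TPM (n = 4) to 147.6 ± 17.1 (n = 4; log2 -1.49 ± 0.09 SE, adjusted p = 5.42e-11), and Stat2 from 37.0 ± 15.0 to 10.56 ± 3.29 (-1.69). Irf1 fell from 187 ± 24.0 to 62.5 ± 17.1 (-1.60), Irf9 from 36.1 ± 4.19 to 21.2 ± 5.27 (-0.76), Irf7 from 85.7 ± 67.1 to 19.5 ± 16.3 (-2.14, adjusted p = 0.00292) and Ifng from 2.39 ± 1.00 to 0.133 ± 0.112 (-1.55, adjusted p = 0.0203). Ly6a, an interferon-inducible surface marker, showed the largest drop among named genes, from 515 ± 239 to 15.3 ± 5.98 TPM (-4.93). Il12rb2, which encodes a chain of the IL-12 receptor and is induced during Th1 differentiation, fell by 3.81, Isg15 by 3.44, and the GTPases Gbp10 by 3.00 and Iigp1 by 2.71 on the log2 scale. Fewer genes rose, among them Pou2af1 (log2 1.39), Xcl1 (1.35), Klf2 (1.22) and Nt5e (1.20). Of 77 type I genes 0 rose and 62 fell (68 list-wise; median -1.07, camera adjusted p = 1.6e-49, and 0.0252 when estimated). The list of IFN-γ, class II and GTPase genes had 38 of 46 lower (40 list-wise; median -1.08, camera adjusted p = 1.17e-42, and 0.00832 when estimated). The Th1 list had 12 of 29 lower and 1 higher (15 and 1 list-wise; camera adjusted p = 3.26e-07, and 0.0148 when estimated). Of the genes that IFN-β induced in WT cells at 24 h, 211 fell and 0 rose (237 and 0 list-wise; camera adjusted p = 2.23e-79, and 0.00714 when estimated). Of 81 that IFN-γ induced there, 73 fell (77 list-wise; camera adjusted p = 5.68e-77, and 0.00164 when estimated). B cell markers moved slightly up (1 of 9 higher, also 1 list-wise; median 0.27, camera adjusted p = 0.0274, and 0.396 when estimated), but with the series as a covariate the median was -0.035 (adjusted p = 0.914). Macrophage markers moved down (2 of 4, also 2 list-wise, camera adjusted p = 0.00696, and 0.0252 when estimated), as did dendritic markers (1 of 2, and 2 list-wise; median -1.08, camera adjusted p = 0.00963, and 0.0481 when estimated). In all 344 genes were higher and 871 lower. This total of 1215 was 639 with only these libraries, 554 with the series as a covariate, about 2.2e+02 within the shared series (2 libraries against 1 WT) and 793 without Tbx21-/- neutral replicate 3. Within the series Stat1 differed by -1.31, Stat2 by -2.11, Irf7 by -3.40 and Ly6a by -5.58, while the calls of Irf7 and Isg15 were lost with only these libraries and that of Ifng with the covariate.

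With IFN-γ the direction turned, and type I interferon-stimulated genes stood higher without T-bet. The 3 Tbx21-/- libraries (1 with IFN-γ alone and 2 of the Iso arm) were compared with 3 WT libraries. Cxcl10 rose from 1.94 ± 0.520 to 74.0 ± 28.2 TPM (log2 4.61 ± 0.57 SE, adjusted p = 5.69e-06). Ifit3 rose from 5.01 ± 2.44 to 91.1 ± 47.7 (3.89), Oas1a from 5.48 ± 2.87 to 63.1 ± 4.56 (3.39), the antiviral membrane protein gene Ifitm3 from 21.8 ± 2.35 to 172 ± 20.3 (2.92) and Rsad2 from 4.97 ± 2.43 to 43.8 ± 19.8 (2.90). Irf7 rose from 116 ± 35.9 to 407 ± 41.0 TPM (1.84, adjusted p = 0.0147), Stat2 from 42.0 ± 5.07 to 90.3 ± 5.32 (1.09), Stat1 from 397 ± 48.4 to 609 ± 13.2 (0.62) and Irf9 from 43.5 ± 5.95 to 60.8 ± 2.41 (0.48, adjusted p = 0.016). Irf1 was 238 ± 33.4 against 156 ± 23.9 TPM (adjusted p = 0.11). Ifnb1, a type I interferon gene, was low in both genotypes, at 2.33 ± 3.15 against 0.207 ± 0.179 TPM (1.07, adjusted p = 0.0384). The library with IFN-γ alone (5.96 TPM) carried this rise, which was 0.33 without it (adjusted p = 0.3; exact permutation p with it 0.2). Th1 effector genes went the other way: Nkg7 fell from 139 ± 20.0 to 9.79 ± 1.34 TPM (-3.70) and Ifng from 14.5 ± 10.9 to 0.83 ± 0.239 (-2.69, adjusted p = 0.000352). Other genes that fell were Selenbp1 (-3.34), the receptor gene Acvrl1 (-2.53) and the kinase gene Matk (-2.25).

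As groups, 70 of 77 type I genes rose and 0 fell (76 and 0 list-wise), with a median log2 change of 1.38 (camera adjusted p = 4.88e-54, and 0.0371 when estimated). The IFN-γ, class II and GTPase list had 30 of 46 higher and 2 lower (37 and 2 list-wise, camera adjusted p = 4.77e-20, and 0.0801 when estimated). Sensors of nucleic acids were 9 of 16 higher and 1 lower (10 and 1 list-wise, camera adjusted p = 4.86e-07, and 0.0371 when estimated). Of 7 type I interferon ligands measured 2 rose (7 list-wise, camera adjusted p = 0.000847, and 0.32 when estimated). The Th1 list had 9 of 29 lower and 1 higher (13 and 3 list-wise, camera adjusted p = 0.00496, and 0.161 when estimated). Interferon receptor, JAK-STAT and IRF genes were 8 of 28 higher and 1 lower (10 and 1 list-wise, camera adjusted p = 0.00127, and 0.129 when estimated). Of 2 dendritic markers 1 rose (1 list-wise; median 1.01, camera adjusted p = 0.0354, and 0.129 when estimated), and of 15 heat shock genes 2 (2 list-wise, camera adjusted p = 0.0354, and 0.374 when estimated). Summed over the type I list, TPM reached 14120 ± 1006 in Tbx21-/- and 6348 ± 814 in WT libraries. Markers of other cell types summed to 540 ± 123.9 against 250.8 ± 25.9 TPM, mostly through Ccl5 (310.1 against 98.9), which T cells also express. The 9 dendritic ones in no other list summed to 2.44 against 1.62 TPM, so dendritic calls at 72 h cannot show dendritic cells. Of 13277 genes 888 were higher and 1382 lower. The total of 2270 was 855 with only these libraries, 801 within the shared series and 3838 with the series as a covariate. With the covariate the type I median was 1.11 and 57 genes passed. The shared series held 1 library of each genotype, too few to judge calls; there the median was 1.45, and Ifng, Irf9, Stat1, Stat2 and Acvrl1 did not pass. The covariate ended those of Irf7 (log2 1.00) and Irf9 (0.35).

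IFN-β left few genotype differences at 72 h. Irf7 measured 482 ± 101 TPM in Tbx21-/- (n = 4) and 403 ± 83.3 in WT libraries (n = 5; adjusted p = 0.926), Stat1 556 ± 21.7 against 540 ± 34.04 (0.938), Stat2 75.3 ± 12.1 against 77.0 ± 5.83 (0.981), Irf9 69.1 ± 2.25 against 61.3 ± 5.47 (0.683) and Irf1 129 ± 56.8 against 151 ± 8.91 (0.685). Th1 genes remained lower: Ifng was 3.07 ± 2.13 against 18.8 ± 7.03 TPM (log2 -2.37 ± 0.40 SE, adjusted p = 0.00205). Nkg7 fell by 2.88, Il12rb2 by 2.10, Ly6c2 by 1.89, the transcription factor gene Irf8 by 1.88 and Klrk1 by 1.78 on the log2 scale. Rorc, which encodes the Th17 factor RORγt, rose from 1.4 ± 0.497 to 8.99 ± 2.90 TPM (2.04, adjusted p = 5.43e-06), Ccr4 by 1.28 and Dynlt1b by 1.00. Of 77 type I genes 0 rose and 1 fell, also list-wise, with a median of 0.08 (camera adjusted p = 0.0351, and 0.922 when estimated); the median was 0.0051 with the series as a covariate. The Th1 list had 7 of 29 lower and 1 higher (13 and 1 list-wise; camera adjusted p = 5.19e-16, and 0.000821 when estimated). Th17 genes had 2 of 10 higher (3 list-wise, camera adjusted p = 0.003, and 0.145 when estimated). B cell markers had 2 of 9 higher (4 list-wise; median 0.70, camera adjusted p = 0.000635, and 0.388 when estimated), a call lost with the series as a covariate (median 0.29, adjusted p = 0.393). In total 58 genes were higher and 96 lower. That sum of 154 was 24 with only these libraries, 186 higher and 102 lower with the covariate, 9 within the shared series and 77 without Tbx21-/- IFN-β replicate 3. Within the series the calls of Ifng, Nkg7, Il12rb2, Ly6c2, Irf8, Klrk1 and Rorc were lost, and with only these libraries those of Ifng, Il12rb2 and Irf8.

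Against their neutral cultures, Tbx21-/- cells responded strongly to both interferons. With IFN-γ, Irf7 rose from 19.5 ± 16.3 TPM (n = 4) to 407 ± 41.0 (n = 3; log2 4.67 ± 0.48 SE, adjusted p = 7.4e-08), Stat2 by 3.03, Stat1 by 2.05, Irf1 by 1.94 and Tbx21 by 1.04. Ly6c1 (7.46), Ly6a (6.50), Isg15 (6.14) and Cxcl10 (5.81) rose most among the named genes, and Ifnb1, listed at 0 in each neutral library, rose by 1.33 (adjusted p = 0.00337), or by 0.59 without the library with IFN-γ alone (adjusted p = 0.018). All 77 type I genes rose, also list-wise (median 2.93, camera adjusted p = 7.1e-72, and 0.00842 when estimated). With IFN-β the median was 3.09, again with 77 of 77 higher (77 list-wise), and Plac8 rose from 1.09 ± 0.490 to 384 ± 62.7 TPM (7.54), Irf7 by 4.90, Stat2 by 2.76, Stat1 by 1.91, Ifng by 1.69 and Irf1 by 0.97. The imprinted gene Dlk1 fell with either interferon (-2.90 with IFN-γ and -2.83 with IFN-β), as did Igfbp4 (-1.99 and -2.82), and Aldoc fell with IFN-β (-3.18). Cell cycle genes had 20 of 40 lower and 1 higher with IFN-γ (22 and 1 list-wise, camera adjusted p = 1.4e-05, and 0.12 when estimated). Of 2 dendritic markers 2 rose with IFN-γ and with IFN-β, also list-wise (camera adjusted p = 0.00229 and 0.00532, 0.0289 and 0.0571 when estimated). Of 4 macrophage markers 2 rose with each and 1 fell with IFN-γ, the same list-wise (camera adjusted p = 0.0171 and 0.0361, and 0.0467 and 0.0836 when estimated). Heat shock genes rose with each, 4 and 6 of 15 (3 and 12 list-wise, camera adjusted p = 0.0212 and 0.000243, and 0.318 and 0.0836 when estimated). IFN-γ called 2026 genes higher and 2187 lower, a total of 4213 that was 1709 within the shared series and 2591 with the single IFN-γ library lacking the Iso arm. IFN-β called 2488 higher and 1697 lower, a total of 4185 (2248 within the series).

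The interaction of genotype and interferon compared these responses. For IFN-γ it was positive for Cxcl10 (6.02 ± 0.75 SE, adjusted p = 5.57e-06), Ly6a (5.63), Irf7 (3.97), Stat2 (2.78), Irf1 (2.20), Stat1 (2.11), Irf9 (1.25) and Tbx21 (1.02) on the log2 scale, and negative for the chemokine gene Xcl1 (-2.03). Ifnb1 stood at 1.31 (adjusted p = 0.0597) and Ifng at -1.15 (0.249). It was positive for 76 of 77 type I genes (77 list-wise; median 2.78, camera adjusted p = 7.57e-77, and 0.00763 when estimated). So it was for 40 of 46 IFN-γ, class II and GTPase genes, with 1 negative (41 and 1 list-wise; camera adjusted p = 1.15e-42, and 0.00695 when estimated). For IFN-β it was positive for Ly6a (4.47), Gbp10 (2.94), Stat2 (1.64), Stat1 (1.53), Irf1 (1.27, adjusted p = 0.0337) and Irf9 (0.94) and negative for Xcl1 (-2.04), and Irf7 stood at 2.39 (adjusted p = 0.0507). Here 35 of 77 type I genes passed (68 list-wise; median 1.11, camera adjusted p = 2.47e-66, and 0.0117 when estimated). Positive too were 2 of 4 macrophage markers for each interferon (2 list-wise, camera adjusted p = 0.00763 and 0.000596, and 0.0279 and 0.0092 when estimated) and 2 and 1 of 2 dendritic markers (2 and 1 list-wise, camera adjusted p = 0.00519 and 0.00416, and 0.0327 and 0.0333 when estimated). The counts were 2036 genes for IFN-γ (1061 positive) and 174 for IFN-β (152 positive). With only the compared groups they came to 1318 and 108, with the series as a covariate to 3635 and 471, and for IFN-γ within the shared series to 664.

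**Figure D2:**
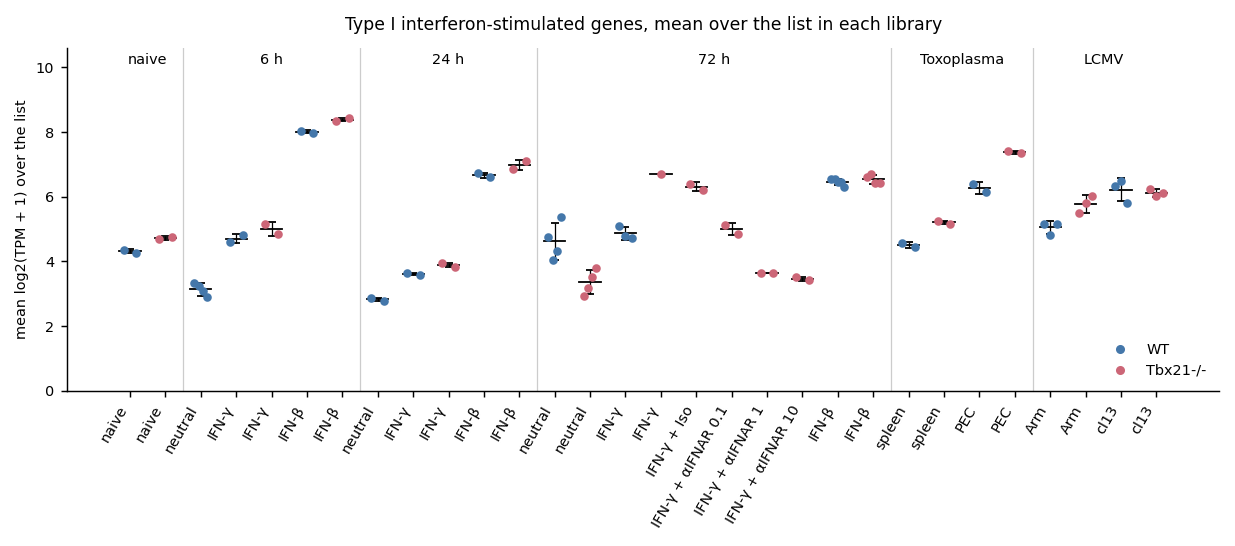
Mean log2(TPM + 1) over the type I interferon-stimulated list in each RNA library, by group. Black lines are means, bars SD, blue points WT and red Tbx21-/-. At 72 h Tbx21-/- libraries lie below WT in neutral culture and above WT with IFN-γ, and anti-IFNAR lowers the list.

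Blocking the type I interferon receptor lowered type I genes of IFN-γ-treated Tbx21-/- cells. At dose 10, Irf7 fell from 391 ± 43.3 TPM in the Iso arm (n = 2) to 6.47 ± 1.87 (n = 2; log2 -5.73 ± 0.64 SE, adjusted p = 1.28e-06). Oasl2 fell from 206.2 ± 32.5 to 1.64 ± 0.113 (-6.29), Isg15 from 567 ± 103 to 8.31 ± 0.0919 (-5.92), Ifit3 from 64.3 ± 15.3 to 0.17 ± 0.0566 (-5.78), Stat2 from 88.5 ± 6.12 to 14.8 ± 1.31 (-2.50) and Irf9 from 60 ± 2.86 to 23.1 ± 2.07 (-1.34). Stat1 (503 ± 48.2 against 602 ± 7.64, adjusted p = 0.134), Irf1 (233 ± 40.1 against 223 ± 28.5, 0.915) and Ifnb1 (0.015 ± 0.0212 against 0.52 ± 0.297, 0.0531) did not pass. Rising genes included Selenbp1 (0.975 ± 0.219 to 18.4 ± 2.81 TPM, 3.29), Acvrl1 (3.19), the lymphoid polymerase gene Dntt (2.50) and Tbx21 itself (12.1 ± 0.778 to 18.3 ± 0.552, 0.56, adjusted p = 0.0213). Of 77 type I genes 76 fell and 0 rose (77 and 0 list-wise; camera adjusted p = 1.43e-54, and 0.0427 when estimated). Their median was -2.62, or -2.50 relative to the median of all genes. The IFN-γ, class II and GTPase list had 22 of 46 lower and 1 higher (25 and 1 list-wise; median -0.65, camera adjusted p = 0.000168, and 0.447 when estimated). Among T cell activation genes 11 of 24 were lower (13 list-wise, camera adjusted p = 0.00626, and 0.36 when estimated). Among cytotoxic genes 8 of 15 were lower (10 list-wise, camera adjusted p = 0.00226, and 0.0427 when estimated).

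Lower doses of anti-IFNAR lowered type I genes as well. At dose 1 Irf7 measured 12.0 ± 0.375 TPM (-4.91), Stat2 18.7 ± 0.0354 (-2.19), Ifit3 0.25 ± 0.0141 (-5.69), Oasl2 2.24 ± 0.0212 (-5.99) and Isg15 12.1 ± 0.141 (-5.42), while Acvrl1 (3.51), Selenbp1 (3.34) and Tbx21 (20.2 ± 0.396, 0.69, adjusted p = 0.00495) were higher. At dose 0.1 Ifit3 (2.57 ± 1.103 TPM, -4.21), Rsad2 (-2.81) and Ifitm3 (-2.48) fell and Selenbp1 (2.55) and Acvrl1 (2.48) rose. Irf7 at 114 ± 17.2 TPM (adjusted p = 0.131), Stat2 at 48.1 ± 4.71 (0.0941) and Tbx21 at 17.9 ± 0.969 (0.0913) did not pass at that dose, but did with the series as a covariate. Type I genes had 76 of 77 lower at dose 1 (76 list-wise; median -2.50, camera adjusted p = 2.38e-49, and 0.0544 when estimated). At dose 0.1 it was 45 (67 list-wise; median -1.17, camera adjusted p = 1.23e-42, and 0.0847 when estimated). Genes called numbered 3210 at dose 10 (749 higher), 3373 at dose 1 (829 higher) and 530 at dose 0.1 (159 higher). After quantile normalization, which moved the median of all genes by 0.13 at dose 10 and 0.12 at dose 1, the share called higher at dose 10 went from 23.3 to 50.0% and the type I median was -2.47. Leaving out Iso replicate 1 gave 1717 and 1853 genes at doses 10 and 1, and leaving out replicate 2 of dose 0.1 gave 65 there, against 1425 with the series as a covariate. The 2 sets of consecutive library numbers as a block gave 3081, 3205 and 449. Calls of Tbx21 were lost at dose 10 without any 1 of the 4 libraries and at dose 1 without Iso replicate 1.

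At 6 h both interferons raised most interferon-stimulated genes in WT cells. IFN-γ raised Gbp2 from 15.4 ± 5.71 TPM (n = 4) to 918 ± 63.3 (n = 2; log2 5.87 ± 0.22 SE, adjusted p = 4e-12), Ly6a by 5.35, Iigp1 by 5.34, Tbx21 by 4.64, Tbkbp1, the gene next to Tbx21 on chromosome 11, by 4.47, Stat1 by 3.35, Irf1 by 3.05, Irf7 by 2.51, Stat2 by 1.83 and Irf9 by 1.55. Xcl1 fell by 2.55. IFN-β raised Ifit3 from 2.07 ± 0.210 to 986 ± 40 TPM (8.33), Rsad2 by 7.78, Mx1 by 7.01, Irf7 from 17.5 ± 2.28 to 1795 ± 9.10 TPM (6.61), Stat1 by 4.13, Stat2 by 3.83, Tbx21 by 3.69, Irf9 by 2.56 and Irf1 by 1.81, and lowered Xcl1 (-4.26) and the receptor gene Cd160 (-2.17). Type I genes had 67 of 77 higher with IFN-γ (71 list-wise; median 1.33, camera adjusted p = 7.89e-96, and 0.00169 when estimated). IFN-β raised 77 (77 list-wise; median 4.72, camera adjusted p = 1.16e-138, and 0.00019 when estimated). The IFN-γ, class II and GTPase list had 40 of 46 higher with IFN-γ (40 list-wise, camera adjusted p = 2.15e-98) and 39 with IFN-β (39 list-wise, camera adjusted p = 1.09e-56), both held when estimated. IFN-γ called 547 genes higher and 117 lower, and IFN-β 1189 higher and 2258 lower. With only the compared libraries these totals of 664 and 3447 came to 219 and 1593, and without replicate 1 of the treated group to 306 and 1728.

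At 24 h WT cells still responded to both interferons. With IFN-γ, Ly6a (5.74 ± 0.20 SE, adjusted p = 1.39e-11), Tbx21 (4.89), Iigp1 (4.53), Tbkbp1 (3.804), Irf1 (2.39), Stat1 (2.09), Irf7 (1.78), Irf9 (0.91) and Stat2 (0.76) were higher on the log2 scale, Ifng rose from 0.125 ± 0.0212 to 2.34 ± 0.375 TPM (1.56, adjusted p = 0.0199), and Ccr4 (-1.53) and Rorc (-1.36) were lower. IFN-β kept Isg15 (7.88), Plac8 (7.75), Ifit3 (7.32), Irf7 (7.28), Tbx21 (3.18), Stat2 (2.99), Stat1 (2.64), Ifng (1.63) and Irf1 (1.36) higher, whereas the mitotic spindle gene Nusap1 (-1.96) and Fgf2 (-1.92) fell. Type I genes had 32 of 77 higher with IFN-γ (48 list-wise; median 0.52, camera adjusted p = 1.74e-66, and 0.00594 when estimated) against 76 with IFN-β (77 list-wise; median 3.67, camera adjusted p = 1.28e-166, and 9.05e-05 when estimated). Cell cycle genes fell with IFN-β, 26 of 40 passing (34 list-wise; median -0.92, camera adjusted p = 1.61e-23, and 0.0403 when estimated). Totals were 169 genes with IFN-γ (141 higher) and 1242 with IFN-β (612 higher). With only the compared libraries they were 67 and 1914, and leaving out 1 library gave at lowest 98 (without WT neutral replicate 2) and 652 (without WT IFN-β replicate 1). The calls of Ifng, Irf7, Stat2, Ccr4 and Rorc with IFN-γ were lost with only these libraries.

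Before 72 h the genotype differences in interferon-stimulated genes were small. At 6 h with IFN-γ, Tbx21 fell by 2.27, the galectin gene Lgals7 from 56.2 ± 16.6 to 20.8 ± 7.21 TPM, Rsad1 by 1.12, the IL-12 receptor gene Il12rb1 by 0.98 and the costimulatory receptor gene Tnfrsf9 by 0.81 on the log2 scale in Tbx21-/- cells, while Dynlt1b rose by 1.05. Irf7 (145 ± 30.4 against 105 ± 21.8 TPM, adjusted p = 0.394), Stat1 (949 ± 129 against 716 ± 15.8, 0.371), Stat2 (36.8 ± 6.33 against 28.3 ± 0.665, 0.312), Irf9 (91.8 ± 15.4 against 74.5 ± 3.02, 0.368) and Irf1 (601 ± 42.4 against 473 ± 28.3, 0.646) were all higher in Tbx21-/- means without passing. With IFN-β at 6 h, Stat2 rose from 116 ± 0.219 to 168 ± 3.08 TPM (0.53, adjusted p = 0.0416) and Eomes, a relative of T-bet, from 3.22 ± 0.255 to 14.6 ± 0.976 (1.89), Dynlt1b rose by 1.17, and Rsad1 (-1.18), Tnfrsf9 (-0.95) and Tbx21 (-2.40) fell. At 24 h with IFN-γ, Rorc rose from 1.60 ± 0.226 to 10.56 ± 3.15 TPM (2.13, adjusted p = 0.000556) and Tbx21 (-2.84) fell. At 24 h with IFN-β, Il7r (1.97) and Pik3ip1 (1.55) rose and Gzmb (-1.94), Irf8 (-1.72) and Tbx21 (-2.06) fell. Type I genes were higher in 75 of 77 means at 6 h with IFN-γ, where 0 passed (2 list-wise; median 0.29, camera adjusted p = 3.3e-15, and 0.48 when estimated). With IFN-β at 6 h 4 passed (9 list-wise; median 0.39, camera adjusted p = 1.17e-11, and 0.454 when estimated). At 24 h 0 passed with either interferon (15 with IFN-γ and 5 with IFN-β list-wise, medians 0.31 and 0.31, camera adjusted p = 4.25e-16 and 6.84e-09, and 0.325 and 0.754 when estimated). Naive and resting T cell genes were higher at 24 h with IFN-β, 1 of 19 passing (9 higher and 1 lower list-wise, camera adjusted p = 1.88e-05, and 0.754 when estimated). These comparisons called 22, 583, 6 and 60 genes in the order given. With only the 4 libraries of each comparison limma called 0 genes in each, and leaving out 1 library gave at lowest 1 (without Tbx21-/- replicate 1), 11 (without WT replicate 1), 3 (without Tbx21-/- replicate 2) and 1 (without Tbx21-/- replicate 2).

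Naive Tbx21-/- cells showed higher levels of some interferon-stimulated genes. Oasl1 rose from 4.99 ± 0.212 TPM (n = 2) to 15.0 ± 0.354 (n = 2; log2 1.42 ± 0.19 SE, adjusted p = 0.0016), Ifit3 by 1.38 and Oas1a by 1.00. Irf7 was 145 ± 16.4 against 84.4 ± 2.22 TPM (adjusted p = 0.132), and Stat1 194.8 ± 53.0 against 193.6 ± 1.67 (0.994). The heat shock genes Hspa1a (54.1 ± 13.6 to 13.0 ± 2.30 TPM, -1.97) and Dnajb1 (-0.59) fell. Gm8494 was listed at 0 in both WT libraries and measured 9.74 ± 1.74 TPM in Tbx21-/- cells. Of 77 type I genes 8 rose (28 list-wise; median 0.36, camera adjusted p = 9.93e-24, and 0.235 when estimated). Heat shock genes had 2 of 15 lower (10 lower and 1 higher list-wise; camera adjusted p = 1.42e-08, and 0.235 when estimated). B cell markers had 0 of 14 passing (11 higher list-wise; median 1.20, camera adjusted p = 1.04e-11, and 0.235 when estimated). Erythroid and platelet markers had 0 of 5 passing (4 list-wise; median 2.18, camera adjusted p = 0.00405, and 0.53 when estimated). In all 26 genes were higher and 14 lower. That total of 40 was 0 with only these libraries, 140 after quantile normalization and 748 without Tbx21-/- naive replicate 2.

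During Toxoplasma infection WT and Tbx21-/- cells shared hosts, and without T-bet Th1 genes fell and several Th17 and Th2 genes rose. In PEC, Ifng fell from 1371 ± 494 TPM (n = 2) to 58.2 ± 5.18 (n = 2; log2 -4.49 ± 0.30 SE, adjusted p = 0.000662), Il12rb2 from 146 ± 25.0 to 7.72 ± 2.09 (-4.09), the protease gene Ctse by 3.75 and the macrophage growth factor gene Csf1 by 3.52. The Th17 genes Ccr6 (0.83 ± 0.255 to 41.4 ± 10.2 TPM, 4.52) and Rorc (0.14 ± 0.0283 to 24.7 ± 4.33, 4.49) and the Th2 genes Ccr4 (3.82) and Il13 (3.43) rose. Irf7 rose from 396 ± 95.9 to 1004 ± 75.7 TPM (1.36, adjusted p = 0.00349), Stat1 from 610 ± 5.94 to 1351 ± 110 (1.15), Stat2 from 55.7 ± 0.184 to 116 ± 5.37 (1.05) and Irf9 from 110 ± 1.31 to 143 ± 5.90 (0.38), and Irf1 was 256 ± 0.813 against 288.1 ± 31.6 (adjusted p = 0.245). In the spleen Ifng fell from 333 ± 66.3 to 77.5 ± 21.6 TPM (-2.10, adjusted p = 0.00966), Ctse (-3.48) and Csf1 (-3.24) fell, Il22 rose from 0.77 ± 0.212 to 49.5 ± 20.9 (4.78), Rorc by 4.06 and Ccr6 by 3.90. Irf7 rose from 51.4 ± 4.86 to 126 ± 9.42 TPM in the spleen (1.28, adjusted p = 0.00773), Stat1 by 0.71, Stat2 by 0.69 and Irf9 by 0.56. Siglech, a marker of plasmacytoid dendritic cells, rose from 0.095 ± 0.00707 to 20.1 ± 5.60 TPM there (4.25). Irf1 fell by 0.39 (adjusted p = 0.0425), a call lost without any 1 of the 4 libraries.

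In Toxoplasma infection Th1 genes had 27 of 32 lower and 0 higher in PEC (27 and 0 list-wise; median -1.86, camera adjusted p = 2.81e-16, and 0.163 when estimated). In the spleen 13 of 32 were lower and 1 higher (15 and 1 list-wise, camera adjusted p = 4.3e-09, and 0.216 when estimated). Type I genes had 69 of 77 higher and 1 lower in PEC (71 and 1 list-wise; median 1.02, camera adjusted p = 9.28e-29, and 0.225 when estimated). The spleen had 48 higher and 2 lower (57 and 3 list-wise; median 0.64, camera adjusted p = 1.87e-16, and 0.216 when estimated). Th17 genes had 9 of 18 higher and 4 lower in PEC (9 and 4 list-wise; camera adjusted p = 0.00209, and 0.458 when estimated). In the spleen 11 were higher (11 higher and 2 lower list-wise; camera adjusted p = 9.02e-07, and 0.216 when estimated). Th2 genes had 10 of 19 higher and 2 lower in PEC and 8 higher and 2 lower in the spleen (12 and 4, and 9 and 3, list-wise; camera adjusted p = 0.0103 and 0.00738, and 0.458 and 0.317 when estimated). Follicular helper genes in the spleen had 12 of 20 higher (14 higher and 1 lower list-wise; camera adjusted p = 4.13e-06, and 0.216 when estimated). Regulatory T cell genes were 11 of 21 higher and 3 lower (13 and 3 list-wise; camera adjusted p = 0.00399, and 0.237 when estimated). Cell cycle genes fell at both sites, 34 of 40 in PEC (37 list-wise, camera adjusted p = 1.15e-22, and 0.231 when estimated). In the spleen 23 fell (37 list-wise, camera adjusted p = 9.18e-18, and 0.216 when estimated). In the spleen 7 of 9 dendritic markers rose (8 list-wise, camera adjusted p = 3.53e-06, and 0.216 when estimated). There 3 of 7 natural killer (NK) markers rose (6 higher and 1 lower list-wise, camera adjusted p = 0.0136, and 0.216 when estimated), and 2 of 15 granulocyte markers (2 list-wise, camera adjusted p = 0.0336, and 0.58 when estimated). Macrophage markers summed to 900 ± 801 against 478 ± 447 TPM in PEC and to 542 ± 220 against 187 ± 31.7 in the spleen. With the mean of those markers as a covariate, type I genes kept medians of 1.00 in PEC (71 higher and 1 lower) and 0.51 in the spleen (43 and 1).

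PEC had 1643 genes higher and 1842 lower in Tbx21-/- cells, and the spleen 1369 higher and 708 lower. With only the 4 libraries of each site these totals of 3485 and 2077 were 1806 and 1165, and leaving out WT PEC replicate 2 or Tbx21-/- spleen replicate 1 gave 1631 and 509. With the 2 sets of consecutive library numbers, each holding 1 library of every group, as a block they were 3935 and 2685. The genotype difference was tested between sites as well, with 39 genes more positive and 190 more negative in PEC. Cmpk2 (1.32) and Ifit2 (1.46), both interferon-stimulated, were more positive in PEC, and Itgax (-3.46) and Klrb1b (-4.81) more negative. As a list type I genes were more positive (7 of 77, and 26 list-wise, camera adjusted p = 2.94e-16). More negative were, among others, cell cycle (12 of 40, and 30 list-wise, camera adjusted p = 2.08e-14), Th1 (6 of 32, and 18, 9.57e-12), activation (2 of 24, and 16, 1.75e-09), dendritic (3 of 9, and 8 with 1 higher, 7.17e-05), NK (1 of 7, and 4, 0.000172) and B cell lists (0 of 7, and 2, 0.0103). No list passed when estimated (lowest adjusted p = 0.103). Ifng stood at -2.39 (adjusted p = 0.0593), Stat1 at 0.44 (0.0839) and Irf7 at 0.08 (0.905). That count of 229 was 0 without Tbx21-/- PEC replicate 2, where limma left none past the threshold, and 52 at most when any other library was left out, which ended the calls of these 4 genes in nearly every case.

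**Figure D3:**
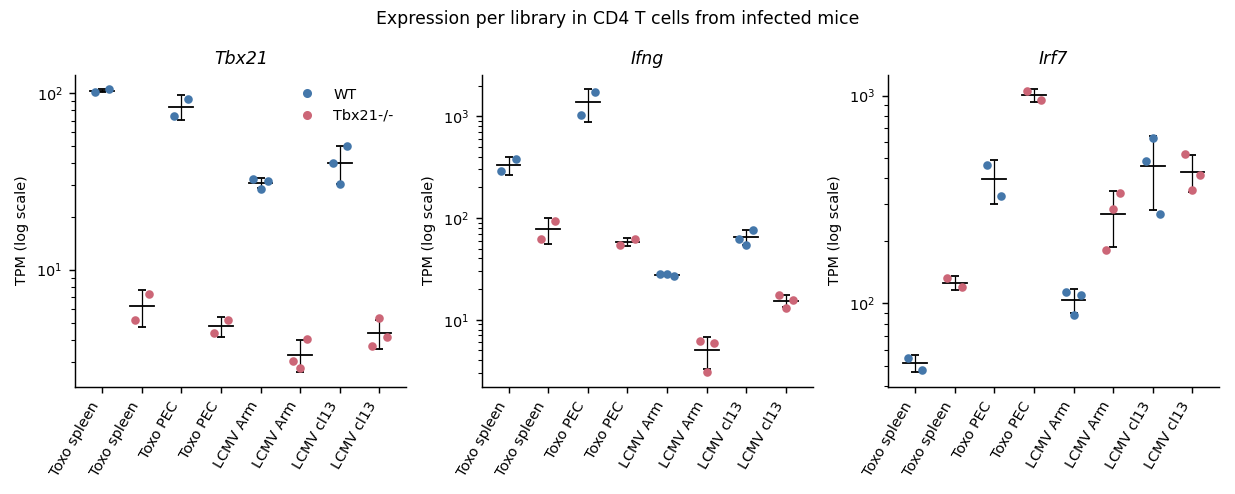
TPM of Tbx21, Ifng and Irf7 on a log axis in each library from Toxoplasma and LCMV infection, by genotype and site or strain. Black lines are means, bars SD, blue points WT and red Tbx21-/-. Tbx21 and Ifng are lower in Tbx21-/- libraries in every setting, and Irf7 is higher in both Toxoplasma sites and with LCMV Armstrong but not with clone 13.

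In LCMV infection Th1 genes fell in Tbx21-/- cells with both strains. With Armstrong, Ifng fell from 27.7 ± 0.792 TPM (n = 3) to 5.03 ± 1.74 (n = 3; log2 -2.30 ± 0.20 SE, adjusted p = 0.000372), the protease gene Ctsw by 3.37, the chemokine gene Ccl5 by 2.89, the NK receptor gene Klrc1 by 2.72, Nkg7 by 2.64 and Il12rb2 by 2.53. Irf7 rose from 104 ± 13.7 to 269 ± 81.0 TPM (1.33, adjusted p = 0.0358), Stat1 from 293.4 ± 44.5 to 529 ± 23.3 (0.86), Stat2 from 18.02 ± 2.60 to 32.6 ± 7.11 (0.81, adjusted p = 0.032) and Irf9 from 58.2 ± 6.60 to 87.3 ± 8.02 (0.58). Ighg1, an immunoglobulin heavy chain gene, rose from 1.803 ± 3.01 to 64.8 ± 39.0 (4.86). Irf1 was 171 ± 11.5 against 134 ± 16.7 TPM (adjusted p = 0.0561). With clone 13, Klrc1 (-4.05), Ccl5 (-4.00), Ctsw (-3.82), Nkg7 (-3.57), Ccl4 (-3.47) and Ifng (64.5 ± 10.8 to 15.4 ± 2.18 TPM, -2.00) fell. The vitamin D receptor gene Vdr rose from 0.433 ± 0.354 to 22.5 ± 6.04 TPM (4.04), and Rorc (3.09), Il1r1 (3.07), Stat1 (0.61) and Irf1 (0.37) rose. Irf7 measured 430 ± 86.7 against 461 ± 180 TPM (adjusted p = 0.969), Stat2 44.6 ± 1.38 against 43.4 ± 9.03 (0.892) and Irf9 107 ± 3.27 against 96.9 ± 8.06 (0.455).

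Type I genes had 30 of 77 higher and 1 lower with Armstrong (58 and 2 list-wise; median 0.73, camera adjusted p = 1.78e-21, and 0.244 when estimated). With clone 13, 2 were higher and 2 lower, also list-wise (median -0.06, camera adjusted p = 0.034, and 0.8 when estimated). The IFN-γ, class II and GTPase list had 24 of 44 higher with Armstrong (39 list-wise, camera adjusted p = 8.27e-26, and 0.0862 when estimated). Clone 13 gave 16 (24 higher and 1 lower list-wise, camera adjusted p = 1.01e-13, and 0.181 when estimated). Th17 genes had 11 of 16 higher with Armstrong (14 list-wise, camera adjusted p = 2.64e-17, and 0.0207 when estimated). Clone 13 gave 12 (13 higher and 2 lower list-wise, camera adjusted p = 7.14e-13, and 0.0529 when estimated). Th2 genes had 9 of 17 and 8 of 17 higher (14 and 13 higher, 0 and 1 lower, list-wise; camera adjusted p = 1.41e-11 and 7.45e-08, and 0.0862 and 0.165 when estimated). Th1 genes had 10 of 33 lower and 1 higher with Armstrong (19 and 4 list-wise, camera adjusted p = 1.15e-15, and 0.107 when estimated). With clone 13, 21 were lower (25 lower and 2 higher list-wise, camera adjusted p = 2.47e-22, and 0.0673 when estimated). Among markers of other cells, 3 of 8 macrophage markers were higher with Armstrong (5 list-wise, camera adjusted p = 0.012, and 0.128 when estimated). With clone 13 higher were 4 of 11 B cell markers (6 higher and 3 lower list-wise, camera adjusted p = 0.043, and 0.476 when estimated). So was 1 of 2 CD8 markers (2 list-wise, camera adjusted p = 0.043, and 0.235 when estimated). Armstrong called 480 genes higher and 123 lower, and clone 13 462 higher and 318 lower. With only the compared libraries these totals of 603 and 780 were 138 higher and 60 lower, and 1294, and they came to 244 without Tbx21-/- Armstrong replicate 2 and to 360 without WT clone 13 replicate 3. The Armstrong calls of Irf7, Irf9, Stat2 and Ccl5 were lost with only these libraries, and the clone 13 call of Irf1 without any 1 library.

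Clone 13 raised interferon-stimulated genes over Armstrong in WT cells. Ifit3 rose from 11.0 ± 2.51 TPM (n = 3) to 86.5 ± 44.7 (n = 3; log2 2.72 ± 0.45 SE, adjusted p = 0.00443), Oasl1 by 2.44, Rsad2 by 2.41, Irf7 from 104 ± 13.7 to 461 ± 180 TPM (2.07), Stat2 by 1.21, Ifng by 1.18, Irf9 by 0.73 and Stat1 by 0.67. Type I genes had 67 of 77 higher (70 list-wise; median 1.096, or 0.98 relative to the median of all genes, camera adjusted p = 1.54e-25, and 0.378 when estimated). In Tbx21-/- cells 1 of 77 was higher, also list-wise (median 0.35, camera adjusted p = 0.000454, and 0.68 when estimated). There the heat shock genes Hspa1b (3.81) and Hspa1a (3.51) and Ifng (1.48) rose, Mcpt8 (-2.56), a basophil protease gene, and Gzmk (-1.77) fell, and Irf7 measured 430 ± 86.7 against 269 ± 81.0 TPM (adjusted p = 0.194). WT cells had 1865 genes higher and 236 lower, and Tbx21-/- cells 410 and 86; quantile normalization took the share higher from 88.8 to 58.4% and from 82.7 to 57.3%. With only the compared libraries these totals of 2101 and 496 were 516 and 1923; they ranged from 846 (without WT clone 13 replicate 1) to 3452 (without WT Armstrong replicate 1) and down to 73 (without Tbx21-/- Armstrong replicate 1). Adjusted over all genes, limma's interaction of genotype and strain called 0 genes in the main fit (1062 at an unadjusted p under 0.05; 2 without a filter, 4 after quantile normalization, at most 6 with a library left out), and Irf7 stood at -1.36 (adjusted p = 0.395). Over the type I list the interaction was negative for 0 of 77 genes past the threshold (45 list-wise; median -0.75, camera adjusted p = 1.06e-33, and 0.374 when estimated), and heat shock genes tended up (0 of 14, and 2 list-wise, camera adjusted p = 7.85e-05, and 0.374 when estimated).

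ChIP-seq at day 3 gave 23 peak lists, 1 library each, scored by the authors. T-bet, measured in WT cells only, had 8826 peaks with IFN-γ, 4281 with IFN-β and 4112 in neutral culture. ChIP cultures, unlike RNA-seq ones, also received antibodies against IL-4, and against IFN-γ if neutral or with IFN-β. STAT2, a transducer of type I interferon signals, had 13692 peaks in WT and 16171 in Tbx21-/- cells with IFN-β, 6014 and 8288 with IFN-γ, and 7062 and 8105 in neutral culture. Of the 8288 STAT2 peaks of IFN-γ-treated Tbx21-/- cells, 3686 (44.5%, 95% Wilson interval 43.4 to 45.6, covering counting error only) overlapped the WT IFN-γ list by at least 1 bp and 6046 (73.0%) overlapped the WT IFN-β list. Among the 4602 absent from the WT IFN-γ list, 2528 overlapped the WT IFN-β list, as did 1047 of 2400 WT IFN-γ peaks absent from the Tbx21-/- list. STAT1 lists shared little: 149 of 2470 Tbx21-/- IFN-γ peaks (6.03%) overlapped the WT list. Their median scores (61.2 and 56.8) lay near the lowest (50), so this cannot show different binding. H3K27ac, a mark of active enhancers and promoters, overlapped for 30357 of 34895 peaks (87.0%). H3K4m1, a mark of enhancers, had 49617 WT and 51009 Tbx21-/- peaks.

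**Figure D4:**
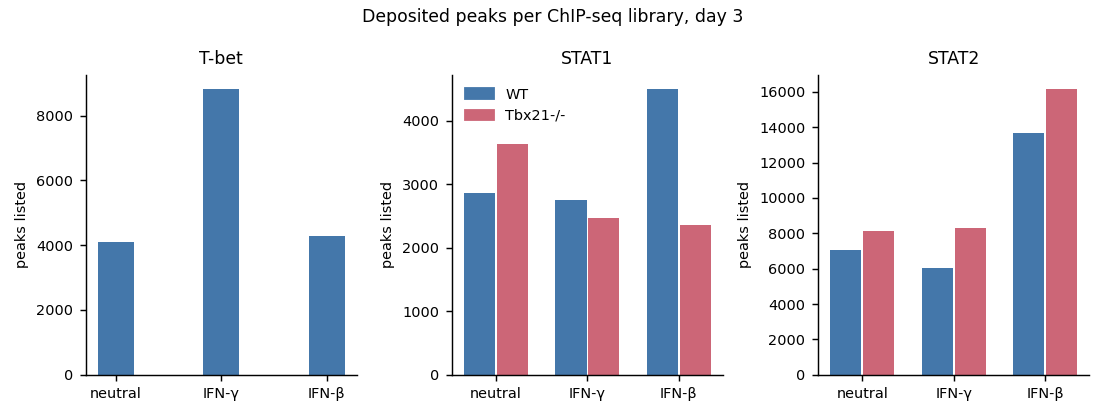
Number of T-bet, STAT1 and STAT2 peaks by genotype and culture (bars from 0, 1 library each, no error). Blue is WT and red Tbx21-/-. STAT2 peaks are most numerous with IFN-β in both genotypes, at 13692 and 16171.

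T-bet peaks lay at several of the genes described above. In IFN-γ-treated WT cells (GRCm38 coordinates) a T-bet peak at chromosome 11, 97126816 to 97127502, lay 11827 bp from Tbx21, and another at chromosome 10, 118440557 to 118441156, lay 190 bp from Ifng (ENSMUSG00000055170). A peak at chromosome 1, 52119179 to 52120034, fell within the span of Stat1, and a peak at chromosome 7, 141265808 to 141266935, within the span of Irf7. The Irf7 peak ranked 7972 by score among 8826. The nearest T-bet peak to Stat2 in that culture was 38367 bp away. Near Irf7, STAT2 peaks at chromosome 7, 141264444 to 141266787 in WT and 141264693 to 141266906 in Tbx21-/- cells with IFN-γ overlapped that T-bet peak. At Stat2 a STAT2 peak at chromosome 10, 128270043 to 128271113, was listed in Tbx21-/- cells with IFN-γ, whereas the nearest in WT cells was 10697 bp away. Th1 genes carried T-bet peaks within 20 kb more often than other genes, 26 of 29 against 43.6% (Fisher's exact test, adjusted p = 1.77e-05). Of genes lower in Tbx21-/- cells with IFN-γ, 689 of 1369 (50.3%) had a T-bet peak near, against 42.9% of other genes (odds ratio 1.35, exact p = 1.69e-07), a difference that did not pass within 5 kb (27.3 against 25.1%, adjusted p = 0.157). Of genes that were higher, 384 of 851 (45.1%) had one, against 43.6% (odds ratio 1.07, exact p = 0.39). STAT2 peaks of Tbx21-/- cells with IFN-γ lay near 558 of these 851 higher genes (65.6% against 59.1% of others, adjusted p = 0.000856). Among WT IFN-γ STAT2 peaks absent from the Tbx21-/- list, 499 of 2400 overlapped a T-bet peak (20.8%). Of shared ones it was 1258 of 3614 (34.8%). Sharing rose with score (60.09 to 69.82% at or above the median), and without matching this cannot judge T-bet dependence.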

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

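The tests of library series, of other cell types, of receptor blockade, of macrophage RNA and of the CD4 share were chosen only after results were seen. Of these, the test by number of markers and the macrophage test over all Toxoplasma libraries were added once the earlier test of the same explanation had been read. The T-bet peak tests and the reassignment of libraries were written before their own results were seen.

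Responses to interferon at 72 h were marked because the interaction with genotype passed. For IFN-γ this held for 2036 genes, among them Irf7 (3.973), Stat2 (2.779), Irf1 (2.202), Stat1 (2.11), Irf9 (1.245) and Tbx21 (1.015). For IFN-β it held for 174 genes, with Stat2 at 1.644, Stat1 at 1.531, Irf1 at 1.273 and Irf9 at 0.9384. List medians for IFN-γ were 2.779 for type I genes, 1.774 for IFN-γ, class II and GTPase genes, 0.51 for JAK-STAT and IRF genes, 1.082 for sensors, 0.8264 for macrophage markers, 2.088 for dendritic markers, 1.811 for IFN-β-induced genes and 2.185 for IFN-γ-induced genes. For IFN-β the same lists had medians of 1.114, 0.9236, 0.1831, 0.5601, 0.5504, 1.104, 0.839 and 1.123. For type I genes the genotype difference had a median of -1.072 in neutral culture and 0.07613 with IFN-β. Their IFN-β interaction thus came mostly from the lower neutral level of Tbx21-/- cells. Between Toxoplasma sites the genotype difference differed for 229 genes.

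Of 146 group values with 4 or more libraries, 4 (2.74%) held a library far from the others, where chance alone gives about 1 in 20. These were Plac8 in Tbx21-/- neutral replicate 4 (1.82 TPM), Ifnb1 in WT IFN-β replicate 5 (0.79), Slc2a3 in the same library (70.05) and Stat1 in WT neutral replicate 4 (492.8).

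Higher type I genes in Tbx21-/- cells with IFN-γ at 72 h could come from library series, from other cells or from type I interferon signalling. With the series as a covariate 57 genes passed (median 1.109, camera adjusted p = 9.94e-22), which argues against the series as the whole cause; within the shared series, with 1 library of each genotype, the median was 1.45 (quartiles 0.9645 to 2.212). Markers of other cells, mostly Ccl5, rose by 3.727% of the rise in the list, which cannot separate the explanations, and at most 2 markers of any other cell type (Ctss and Mpeg1, of 20 macrophage markers) reached 5 TPM, which argues against many such cells. Lyz2 stayed at 0 against 0.01 TPM and C1qb at 0.0067 against 0.01. Blocking the type I interferon receptor in Tbx21-/- cells gave a median of -2.621, which goes with signalling through that receptor in them. No WT library received the antibody, so this test cannot tell whether such signalling made the genotype difference.

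In PEC, type I genes were also higher in Tbx21-/- cells, where macrophage RNA might contribute. The Tbx21-/- library with fewer macrophage transcripts (333.8 TPM summed) against the WT library with more (794.2) still gave a median of 0.8292, with 74 of 77 genes above 0, a comparison of single libraries that cannot tell. With the marker mean as a covariate the PEC median was 0.9951 (quartiles 0.6606 to 1.268, 71 genes higher and 1 lower), which argues against macrophage RNA as the whole cause. Cd4 and Cd3e differed by at most 0.01031, which leaves a smaller share of CD4 RNA open: the bound of 0.3 set for this test was too wide, as 2 SE of these abundant transcripts would hide a loss of 6.083%.

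Genes that were lower in Tbx21-/- cells with IFN-γ lay near T-bet peaks more often (odds ratio 1.35, exact p = 1.69e-07), and genes that were higher did not (odds ratio 1.065). This may reflect activation by T-bet at the former, but at 5 kb the odds ratio was 1.121 (exact p = 0.081), at 100 kb 1.581 and for peaks at or above the median score 1.26.

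Reassigning the libraries to groups gave at most 52 genes for Tbx21-/- against WT in neutral culture (1215 as labelled), 49 with IFN-β (154), 71 for IFN-β against neutral in Tbx21-/- cells (4185), 1881 for the same in WT cells (3368), 844 for IFN-γ in WT cells (1315), 2452 in Tbx21-/- cells (4213) and 2797 for IFN-β against IFN-γ (4858), always with 1 split, the labelled one, as high. For the interactions, 1 split of 100 reached 2036 (highest other 1456) and 4 of 100 reached 174 (highest 527). Tbx21-/- against WT with IFN-γ (highest other 1) and the LCMV comparisons (highest others 1, 2, 1 and 3) had 10 splits each, too few to judge. All 100 splits reached the 0 genes of the LCMV interaction that limma called, the highest giving 3575 by exchanging genotype within a strain.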

How the results depend on the processing

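The fits listed as added in the first section were tests chosen only after results were seen. Replicate numbers follow the order of accessions and no label gives pairs; sets of consecutive library numbers with 1 library of each group were tried as blocks for Toxoplasma (spleen 2685, PEC 3935, site interaction 343), anti-IFNAR (3081, 3205, 449) and WT cells (6 h 548 and 3126, 24 h 147 and 1085). No limit of detection is given, and no planned count model was run, as TPM keeps no counts. Where a value moved, the cause was not tested, though some alternatives used fewer libraries.

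Of 325 pairs of a named gene and a comparison, 271 passed, 176 of them under every alternative run for that pair. Ifng with IFN-γ in WT cells went from 1.837 to -0.4013 within the shared series, where 1 library against 1 cannot show a reversal. Calls lost and gained were 7 and 4 with the pseudocount 0.25, 14 and 0 without a filter, 2 and 3 with quantile normalization, 53 and 4 with only the compared libraries, 6 and 7 with the series covariate, 32 and 3 within the shared series, 44 and 6 when a library was left out, 1 and 0 without the lowest-numbered libraries, 0 and 0 with 2 neutral libraries at 6 h, and 1 and 1 with the macrophage covariate and with blocks. With the covariate, B cell markers in neutral culture went from 0.2678 to -0.03499 and type I genes with IFN-β from 0.07613 to 0.005081, and B cell markers with IFN-β from 0.6999 to 0.2898. An estimated correlation left 80 of 315 list calls.

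Using only the compared libraries gave, for IFN-γ in WT cells at 72 h, 149 genes; for Tbx21-/- against WT 639 (neutral), 855 (IFN-γ) and 24 (IFN-β); for the interactions 1318 and 108; at 6 h 219 and 1593 and at 24 h 67 and 1914 (IFN-γ and IFN-β, WT); for genotype at 6 h, at 24 h and in naive cells 0 each by limma; for Toxoplasma spleen 1165 and PEC 1806; for LCMV Armstrong 2.0e+02, clone 13 1294, and clone 13 against Armstrong 516 (WT) and 1923 (Tbx21-/-). The series covariate gave 3377 for IFN-γ in WT cells, 554, 3838 and 2.9e+02 for genotype (neutral, IFN-γ, IFN-β), 3635 and 471 for the interactions and 1425 for anti-IFNAR 0.1. Within the shared series there were 19, 385 and 1830 (WT IFN-γ, IFN-β, IFN-β against IFN-γ), 2.2e+02, 801 and 9 (genotype), 1709 and 2248 (Tbx21-/- IFN-γ and IFN-β) and 664 (IFN-γ interaction). The IFN-γ library alone gave 2591 for IFN-γ in Tbx21-/- cells. A pseudocount of 0.25 gave 10 and 3 for genotype with IFN-γ at 6 and 24 h. Without a filter genotype gave 21 (IFN-γ 24 h), 97 (naive), 384 (LCMV Armstrong) and 2 (LCMV interaction). Quantile normalization gave 3 (IFN-γ 24 h), 140 (naive) and 4 (LCMV interaction).

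Leaving out 1 library gave these ranges. At 72 h: IFN-γ in WT 669 (without WT IFN-γ replicate 1) to 1506 (without WT neutral 4), neutral genotype 793 to 1254, IFN-β genotype 77 to 179, anti-IFNAR 10 1717 to 2093, 1 1853 to 2159, 0.1 65 to 246. At 6 h: IFN-γ 306 to 902, IFN-β 1728 to 4525, genotype 1 to 73 (IFN-γ) and 11 to 454 (IFN-β). At 24 h: IFN-γ 98 to 113, IFN-β 652 to 800, genotype 3 to 7 and 1 to 14. Naive 74 to 748. Toxoplasma: spleen 509 to 963, PEC 1631 to 2459, site interaction 0 to 52. LCMV: Armstrong 244 to 1193, clone 13 360 to 715, WT strains 846 to 3452, Tbx21-/- strains 73 to 2.0e+02, interaction 0 to 6 by limma. Within 1.5 times stayed WT IFN-β (2745 to 3380), IFN-β against IFN-γ, genotype with IFN-γ (1620 to 2085), both Tbx21-/- responses and the 72 h interactions.

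Quantile normalization moved the share called higher by over 10 points: WT IFN-β 56.32 to 44.58%, neutral genotype 28.31 to 44.32, Tbx21-/- IFN-β 59.45 to 41.28, IFN-β interaction 87.36 to 76.8, anti-IFNAR 10 23.33 to 50.02, 1 24.58 to 48.61 and 0.1 30 to 54.75, WT IFN-γ 6 h 82.38 to 69.24, genotype IFN-γ 6 h 27.27 to 37.5, 24 h 50 to 33.33, IFN-β 24 h 81.67 to 71.43, spleen 65.91 to 55.84, LCMV Armstrong 79.6 to 58.9, clone 13 59.23 to 45.08, strains 88.77 to 58.36 (WT) and 82.66 to 57.25. It moved the all-gene median from -0.1181 to 0.008763 at anti-IFNAR 10, -0.1117 to 0.01322 at 1 and 0.1149 to -0.01231 between strains in WT cells, where type I medians became -2.473, -2.291 and 0.957.

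Peaks at or above the median score gave overlaps of 88.26 and 89.24% for H3K27ac (from 87 and 88.1), 9.79 and 8.661 for STAT1 (6.032 and 5.382), 68.41 for STAT2 of Tbx21-/- in WT IFN-β (64.55), 78.85 for Tbx21-/- IFN-γ in WT IFN-β (72.95), 50.95 in WT IFN-γ (44.47), 79.41 for WT IFN-β in Tbx21-/- (74.15), 69.82 for WT IFN-γ (60.09), 25.09 for STAT2 with T-bet (29.22), 63.02 for T-bet with H3K27ac (66.36) and 19.4 for neutral in IFN-γ T-bet peaks (12.16). Pairs of list and peaks past the threshold numbered 61, then 98 at that score, 88 at 5 kb and 26 at 100 kb.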

Other observations

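The tests of flanking DNA, consistent genes and overlap with receptor blockade described here were chosen only after results were seen.

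Genes outside the interferon lists moved with receptor blockade at 72 h. Selenbp1 fell from 21.8 ± 4.82 to 1.26 ± 0.508 TPM in Tbx21-/- cells with IFN-γ (n = 3 each) and returned to 18.4 ± 2.81 (n = 2) at anti-IFNAR dose 10. Acvrl1 followed the same course, from 24.0 ± 3.62 to 3.33 ± 0.597 and back to 36.9 ± 1.63 TPM. To keep the libraries independent, genes higher in the single Tbx21-/- IFN-γ library without the Iso arm were compared with the antibody test: of 748 such genes 457 (61.1%) fell at dose 10, where 139 would be expected from the sizes of the sets, and 1 rose (42.2 expected). Of 1063 genes that were lower, 310 rose at dose 10 (59.97 expected). Without the genes of the interferon lists, 280 of 541 fell (92.45 expected) and 308 of 1058 rose (60.95).

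Of about 2.2e+02 immunoglobulin segments tested in LCMV infection, 27 were higher in Tbx21-/- cells with Armstrong and 34 with clone 13, and 0 lower. In the Toxoplasma spleen 9 of 18 were higher. Other-cell markers summed higher in the spleen of Tbx21-/- cells: dendritic 63.7 against 4.03 TPM, B cell 84.2 against 20.1 and granulocyte 1235 ± 815 against 503 ± 141. Toxoplasma WT and Tbx21-/- donors also differed in the CD45 allele, which these libraries do not separate from Tbx21.

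In each of the 4 fits 13 genes passed in at least 1 comparison of genotype, always with 1 sign, in 4 to 9 of the 12 comparisons: Cep57l1, Dynlt1b, Ggt5, Gm8494, Ide, Ifit3b, Igfbp7, Lancl3, Rorc, Sema7a, St3gal4, Tmem181b-ps and Tufm. Dynlt1b (chromosome 17, 6429530 to 6440500) ranged from 0.1384 to 1.166 on the log2 scale and its neighbour Tmem181b-ps (6439002 to 6450994) from 0.3863 to 1.034. Gm8494 (chromosome 5, 146574888 to 146576120) measured 8.47 to 15.24 TPM in the 37 Tbx21-/- libraries and 0 to 11.18 in the 38 WT libraries. Ide (chromosome 19, 37268743 to 37334544) ranged from -1.12 to 0.1222. None of the 13 lay within 10 Mb of Tbx21 (odds ratio 0), where 0.2405 would be expected, so the test of flanking DNA could not tell. By comparison the odds ratio was above 1 in each of the 12, with an adjusted p of 0.0424 by Fisher's exact test for IFN-β at 72 h (odds ratio 3.037, 8 of 226 genes) and for IFN-γ at 6 h (8.86, 3 of 223), and 0.0879 to 0.762 elsewhere.

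T-bet and its partners shared sites unevenly. Of 6014 WT IFN-γ STAT2 peaks, 1757 (29.2%) overlapped a T-bet peak, and 5857 of 8826 T-bet peaks (66.4%) an H3K27ac peak. Of 4112 weak neutral T-bet peaks (median score 56.57), 500 (12.2%) overlapped the IFN-γ list. Among STAT1 peaks of WT IFN-γ cells, 57.4% of those shared with Tbx21-/- cells overlapped T-bet, against 96 of 2602 others (3.69%). For H3K27ac it was 5048 of 30472 shared peaks (16.6%) against 244 of 4117 others (5.93%). Neither was matched for score. STAT1 peaks of Tbx21-/- IFN-γ cells lay near 42 of 77 type I genes and 32 of 46 IFN-γ, class II and GTPase genes. At Ifit3 a STAT1 peak was listed there (chromosome 19, 34588156 to 34588507) with none in the weak WT IFN-γ list. T-bet peaks lay near 28 of 77 type I genes (36.4%, against 43.7% of others), no excess (exact p = 0.206).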
